A study of Homo sapiens with 6 samples.

How the data were processed

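The series holds 6 RNA-seq libraries, 2 in each of 3 groups labelled NC, sh1 and sh4. Per the labels, they come from A549, an established human lung adenocarcinoma cell line, and compare a knockdown group with an NC group. The labels do not spell out NC, sh1 or sh4. Reading sh1 and sh4 as 2 knockdown groups with the same target is an assumption made here from the series title and design text. RNA was extracted with Trizol and libraries followed Illumina protocols, per the labels' protocols. The submitters' processing notes name HISAT2 2.0.5 and the build hg18. The read counter, the gene annotation and the filters are not given in the sources used here.

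Each deposited file gives one FPKM value (fragments per kilobase of gene, scaled to sequencing depth) per gene ID, computed by the authors for a single library. The gene IDs conflict with the labels. All 54532 IDs begin with ENSMUSG, the prefix under which Ensembl lists mouse genes, and 0 begin with the human prefix ENSG. The labels state human cells and the notes name a human build, so the organism of the RNA and the annotation behind the values are unresolved here. Of the IDs, 0 matched the 62700 entries of the human gene name table used here and 0 matched the RefSeq gene table. The files do not pair IDs with names, so no symbol, function, coordinate or gene model is given. The targeted gene, whose name the series title gives as DSTY, was therefore not analysed here, nor were the 32 planned gene lists, of whose 696 symbols 0 matched an ID. The rule for naming genes, fixed before the data were examined, required a symbol and so named none. In its place, 2 IDs that rose and 2 that fell in both knockdown groups are printed, taken by the same ranking (the larger of the smaller fold changes, mean FPKM of at least 5, libraries of the groups not overlapping) without the symbol.

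Whole reads were recovered from the deposited FPKM values. Ratios of low values between libraries fell on whole-number steps, which gave the libraries' relative denominators, and a search for whole gene lengths gave the rest. For 25747 of the 25747 IDs above 0 in any library, whole reads and a whole length rebuilt every value to within 1e-06 FPKM plus a ten-millionth part of the value. On simulated data of the same size, the reads of 99.2% of IDs with at least 60 reads in sum were recovered exactly. For 95.4% of all 24539 simulated IDs they were exact, and how the rest differed was not measured. The recovered denominators were proportional to median-of-ratios size factors computed from the recovered reads (largest departure 2.17e-10%), rather than to the read totals, so the deposited FPKM values already carry a between-library scaling that holds the typical gene constant. The labels do not state this step.

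The design fixed before the data were examined assumed counts. Because the files hold FPKM, the main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with IDs at 1 FPKM or more in at least 2 libraries (12755 IDs), one fit over all 6 libraries, 3 residual degrees of freedom, and a robust empirical Bayes variance. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. The variance trend was set on the mean recovered reads. That choice was made after a first simulated-data test with the trend on mean FPKM had given too many false calls. On simulated reads for 12373 IDs with the trend on reads and the same change in sh1 and sh4, 86.7% of IDs changed by 1 log2 unit and 24.7% of those changed by 0.5 were recovered for sh1 against NC. For sh4 against NC the shares were 85.7% and 21.6%. IDs simulated without change made up 9.9% of the calls for sh1 against NC and 4.5% for sh4 against NC. The comparison of sh4 with sh1, which held no difference there, gave 0 calls. In a second simulation of 12377 IDs, sh4 alone changed. For sh4 against sh1, 78.0% of IDs differing by 1 log2 unit and 14.3% of those differing by 0.5 were recovered. IDs without change made up 5.2% of the calls. Few tested IDs were changed, 97 by 0.5 and 98 by 1 log2 unit in the first simulation, and 98 and 100 in the second. The spread between simulated libraries was a set value, not estimated from these data. The shares therefore describe the simulations and are not estimates of power or false calls for the fits reported below. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The comparisons were sh1 against NC, sh4 against NC, the mean of both against NC, and sh4 against sh1.

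Both knockdown comparisons use the same 2 NC libraries. Their overlap was therefore set beside 100 simulated data sets with unchanged groups and the same spread, and beside the overlap of independent lists. With 2 NC libraries, a split leaves 1 for each group. It was run, after seeing the data, from fits without 1 NC library, in which the lone library is assumed to vary like the other groups and the variance estimates still share libraries. Nothing in the labels says whether replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical. Replicate numbers are shared between groups, but the labels attach no batch or day to them. The alternatives tried were no filter, a mean FPKM of at least 5, a pseudocount of 0.1, a replicate block, a minimum fold, fits on the compared groups alone, and leaving out each library. Added after seeing the data were rescaling libraries to their mean FPKM sum over the same IDs, rescaling them to a common sum about 3 times as large, which also let more IDs through the filter (15431) and lowered the weight of the pseudocount, total-read scaling, limma's voom on the recovered reads and the variance trend on mean FPKM. The fits and normalizations planned for deposited counts were not run as written, and voom and total-read scaling used the recovered reads instead. Figures were drawn with matplotlib 3.10.9.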

Results

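RNA abundance was profiled in 6 libraries labelled as A549 lung cancer cells, 2 each from groups labelled NC, sh1 and sh4. The gene IDs of all libraries carry Ensembl's mouse prefix although the labels state human cells, so genes are given by ID only and group names stand for the libraries labelled so. The labels do not spell out NC, sh1 or sh4, and sh1 and sh4 are read here as 2 knockdown groups. Whether the targeted gene was lowered in sh1 and sh4 was not analysed here. The recovered reads came to 15423886 and 14999786 for NC, 17007929 and 18011798 for sh1, and 17943938 and 17579950 for sh4. In a gene of the median length of 2690 bp, 1 read corresponded to between 0.0201 and 0.0242 FPKM across the libraries. Between 19603 and 20594 IDs were above 0 per library, and between 11826 and 11972 reached 1 FPKM.

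Libraries of a group were close to each other and far from those of the other groups. Across the 12755 IDs tested, the root-mean-square difference in log2(FPKM + 1) was 0.24 between the NC replicates, 0.23 between the sh1 replicates and 0.23 between the sh4 replicates. Between libraries of NC and sh1 it was 0.69 in each of the pairs. It ranged from 0.65 to 0.68 between NC and sh4, and from 0.56 to 0.57 between sh1 and sh4. Replicates differed by more than counting noise, with a chi-square per ID of 4.59 for NC, 2.51 for sh1 and 4.37 for sh4, so none was counted as one library deposited more than once. The first principal component, with 56.1% of the variance, separated NC from both knockdown groups. The second, with 34.4%, separated sh1 from sh4.

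**Figure D1:**
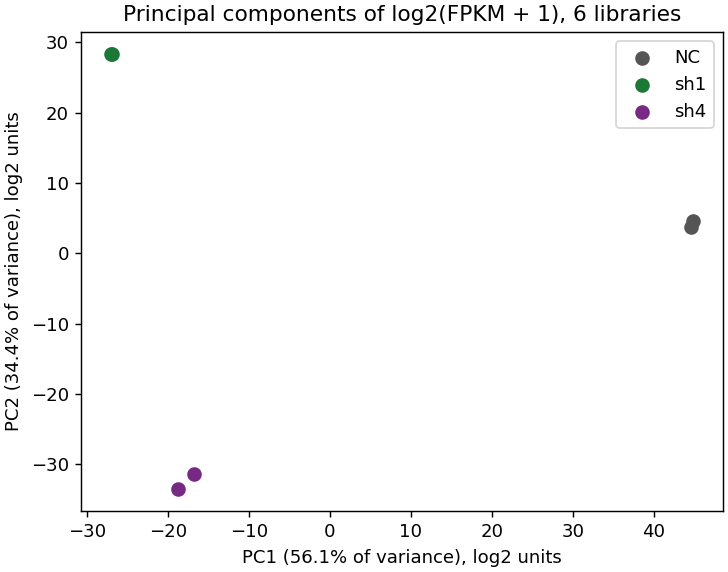
Principal components of log2(FPKM + 1) over 12755 gene IDs; each point is 1 library, coloured by group (the sh1 points overlap), and axes are in log2 units. NC lies at 44.7 and 44.9 on the first component, and sh1 and sh4 lie on its other side and apart from each other on the second.

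The comparison of sh1 with NC asked which transcripts differ between the knockdown group sh1 and the NC group. In sh1, 4128 IDs were higher and 4233 lower than in NC, which is 65.6% of those tested (limma, Benjamini-Hochberg adjusted p below 0.05, n = 2 against 2). The share of higher IDs among these calls was 49.4% as deposited, 44.2% with total-read scaling and 42.9% after rescaling libraries to the same FPKM sum. Most of these changes were small. The median absolute log2 fold change over all IDs was 0.36, against a median standard error of 0.08. Changes of at least 1 log2 unit were found for 724 higher and 548 lower IDs, and changes of at least 2 log2 units for 126 higher and 64 lower IDs. Among the 430 IDs with a mean of 100 FPKM or more, 224 were higher and 120 lower in sh1. Between 20 and 100 FPKM, 874 of 2368 IDs were higher and 957 lower, and between 5 and 20 FPKM, 1655 of 4893 were higher and 1875 lower. Among the 5064 IDs with a mean under 5 FPKM, 1375 were higher and 1281 lower. From the recovered reads, 19 IDs had at most 3 reads in both NC libraries and 30 or more in both sh1 libraries, and 8 IDs showed the reverse.

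The comparison of sh4 with NC asked the same for the sh4 group. In sh4, 4458 IDs were higher and 4230 lower than in NC, or 68.1% of those tested by the same limma fit (n = 2 against 2). With total-read scaling 4616 IDs were higher and 4089 lower, and after rescaling to the same FPKM sum 4707 and 3847. IDs under 200 bp held 8.89% and 12.4% of the FPKM sum in NC, and 5.74% and 6.10% in sh4. Rescaling without these IDs was not run. The median absolute log2 fold change was 0.37. At least 1 log2 unit of change was found for 752 higher and 535 lower IDs, and at least 2 log2 units for 72 higher and 52 lower IDs. Among IDs with a mean of 100 FPKM or more, 189 were higher and 152 lower. Between 20 and 100 FPKM the numbers were 978 and 864, between 5 and 20 FPKM 1820 and 1863, and under 5 FPKM 1471 and 1351. At most 3 reads in both NC libraries with 30 or more in both sh4 libraries was seen for 32 IDs, and the reverse for 5.

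The design text sets knockdown cells as a whole against NC. For the mean of both knockdown groups, weighted equally, 4459 IDs were higher and 4340 lower than in NC by the same fit. An ID changed in 1 group alone can pass this test. Calls in the same direction in both groups were made for 5760 IDs. The balance turned with the scaling, with 4294 higher and 4518 lower under total-read scaling, and 4252 and 4405 after rescaling to the same FPKM sum. It also turned without a change of scaling, with no filter (4402 and 4470) and by voom on the recovered reads (4328 and 4444). The same held with a mean FPKM of at least 5 (2898 and 2970). Leaving out any 1 library of sh1 or sh4 turned the balance as well, and leaving out either NC library did not. With a pseudocount of 0.1 (4405 and 4333) and with the replicate block (4516 and 4420) it did not turn. Nor did it with the variance trend on mean FPKM (4291 and 4222). As deposited, 627 higher and 436 lower IDs changed by at least 1 log2 unit.

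The calls of both comparisons with NC were then set side by side. Both sh1 and sh4 had higher levels of 2872 IDs and lower levels of 2888 IDs than NC, 5760 in all. With changes of at least 1 log2 unit in both, these numbers were 298 and 246. Independent lists of the same lengths would share 1443 higher and 1404 lower IDs. At an unadjusted p under 0.05 in both, 6020 IDs had the same direction. Unchanged groups simulated against common controls gave a mean of 128 such IDs, from 100 to 162, in 100 draws. These draws held no change in either group, so they cannot decide whether changed groups agree. Across IDs, which are not independent replicates, the log2 fold changes of sh1 and sh4 had a Pearson correlation of 0.66 and a Spearman correlation of 0.67. Common controls alone gave a Pearson correlation of 0.50. The covariance of the fold changes was 0.283, and the simulated covariance with no effect was 0.0117. With a separate NC library for each group, a comparison added after seeing the data, 4864 and 4958 of 12417 IDs were called in both in the same direction, for each way of assigning the libraries. Independent lists would share 1240 higher and 1111 lower IDs for either. With 1 NC library common to both groups the numbers were 5071 and 5079 IDs. The covariance was 0.260 and 0.265 with separate NC libraries, against 0.288 and 0.289 with a common one. Part of the overlap may come from the common NC libraries. A shift carried by both NC libraries would also pass the split. The split therefore cannot tell such a shift from a change in sh1 and sh4.

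**Figure D2:**
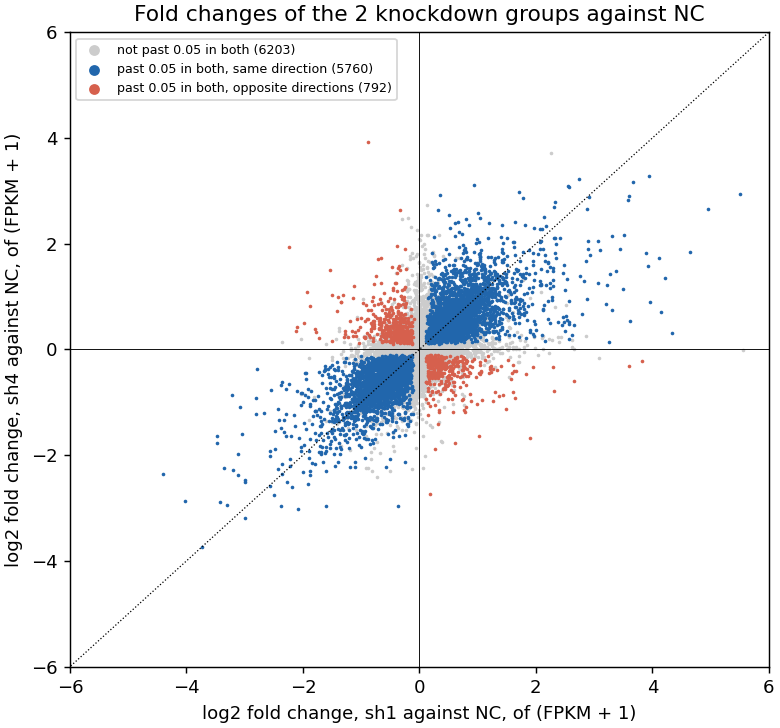
Log2 fold change of (FPKM + 1) in sh4 against NC (y axis) and in sh1 against NC (x axis), 1 point per gene ID, for 12755 IDs. The 5760 IDs past the threshold in both with the same direction lie in the upper right and lower left, and the 792 with opposite directions lie in the other quadrants, 9 of them changed by at least 1 log2 unit in both; the dotted line marks equal changes.

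The ID ENSMUSG00000029371 rose in both groups. Its level was 50.4 ± 4.5 FPKM in NC, 786.9 ± 30.9 in sh1 and 497.2 ± 7.4 in sh4 (mean ± SD, n = 2 each). Its log2 fold change was 3.94 (SE 0.05) in sh1 and 3.28 (SE 0.05) in sh4. ENSMUSG00000025491 rose from 1.26 ± 0.51 FPKM in NC, where the libraries held 28 and 15 reads, to 27.2 ± 0.26 in sh1 and 19.1 ± 0.68 in sh4. Its log2 fold changes were 3.66 and 3.18 (SE 0.12 for both). They were 4.38 and 3.88 with a pseudocount of 0.1, and 4.46 and 3.95 by voom on the recovered reads. ENSMUSG00000029378 fell from 418.6 ± 11.8 FPKM in NC to 30.5 ± 0.25 in sh1 and 30.4 ± 2.3 in sh4, with log2 fold changes of -3.74 in both (SE 0.05). ENSMUSG00000039518 fell from 85.0 ± 2.1 FPKM in NC to 9.88 ± 1.11 in sh1 and 8.42 ± 0.01 in sh4, with log2 fold changes of -2.99 and -3.19 (SE 0.07 for both). The largest adjusted p of these tests was 1.89e-10, for ENSMUSG00000025491 in sh4.

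**Figure D3:**
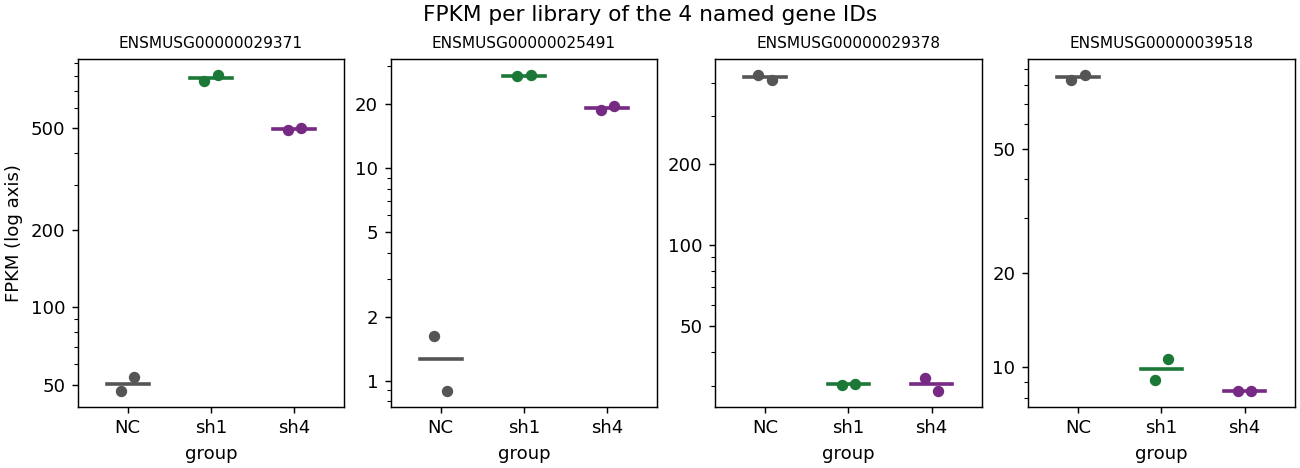
FPKM on a log axis in the NC, sh1 and sh4 groups for the 4 named gene IDs; points are libraries (n = 2 per group) and lines are group means. For each ID, both libraries of sh1 and of sh4 lie beyond both NC libraries.

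The direct comparison of sh4 with sh1 tested where the groups differed. In sh4, 3766 IDs were higher and 3373 lower than in sh1, or 56.0% of those tested by the same limma fit (n = 2 against 2). Of these, 423 higher and 386 lower IDs differed by at least 1 log2 unit. The share of higher IDs among these calls, 52.8% as deposited, was 62.2% with total-read scaling and 67.0% after rescaling libraries to the same FPKM sum, over the same IDs, so the balance of higher and lower IDs depended on the scaling. Of the 5760 IDs changed the same way in both groups, 3039 also differed between sh4 and sh1, with the larger change in sh4 for 1462 and in sh1 for 1577. Opposite directions were found for 792 IDs, of which 348 were higher in sh1 and lower in sh4 and 444 the reverse. Of these 792, the changes of 9 reached 1 log2 unit in both groups. The share higher in sh1 was 43.9% as deposited, 30.9% with total-read scaling and 26.1% after rescaling to the same FPKM sum. Independent lists would give 1369 and 1479 such IDs.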

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

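The comparison of sh4 with sh1 was planned, while the count of opposite directions, the differences of the named IDs and the tests of explanations were chosen after the result was seen. The effect against NC differed between sh4 and sh1, by the direct test of the difference, for 7139 IDs, of which 792 moved in opposite directions in the 2 groups. Among the 4 named IDs, the log2 fold change in sh4 minus that in sh1 was -0.66 for ENSMUSG00000029371, -0.49 for ENSMUSG00000025491 and -0.20 for ENSMUSG00000039518, each past the threshold in limma's test. The call for ENSMUSG00000039518 was lost in fits without sh1 replicate 2 (-0.10, adjusted p = 0.26), sh4 replicate 1 (-0.20, adjusted p = 0.059) and sh4 replicate 2 (-0.21, adjusted p = 0.054), and the difference was -0.31 without sh1 replicate 1. Over all its alternatives the adjusted p reached 0.28. For ENSMUSG00000025491 the difference was -0.49 with no filter (25747 IDs, adjusted p = 0.11), -0.51 with a pseudocount of 0.1 (adjusted p = 0.093) and -0.38 after rescaling to the larger common sum (15431 IDs, adjusted p = 0.13), each no longer past the threshold. It was -0.37 after rescaling to the mean FPKM sum over the same IDs (adjusted p = 0.026). A minimum fold of 1 log2 unit removes these 3 calls by construction. For ENSMUSG00000029378 the difference was -0.0044 (SE 0.05, adjusted p = 0.95, and 0.12 to 1 over its alternatives).

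The pattern weighed is the set of 792 IDs called in both groups with opposite signs. In 100 simulated data sets of one shared response, every sh4 change was 0.96 times the sh1 change. They held a mean of 0.33 such IDs and at most 2. No ID has truly opposite signs in that setting, so a low count was built in. The 792 IDs are more than a difference in strength alone gave there. The simulation cannot decide on a shared response with added variation between groups, such as between cultures, which it left out. Total-read scaling gave 832 IDs with opposite signs and moved their balance. Whether these include all of the 792 is not given here. It shifted the median fold against NC by only -0.05 log2 units in sh1 and 0.02 in sh4. A scaling difference of that size did not lower the count, but the test cannot decide on a larger offset, which stays open. Also open is a difference in culture, handling or library preparation between the groups, for which the labels give no batch. Effects of each knockdown on other transcripts stay open too, if sh1 and sh4 are separate constructs. The labels do not say so and the design does not test it. Of the 792, 113 reached 1 log2 unit in at least 1 group and 9 in both, and the median absolute change was 0.37 in sh1 and 0.36 in sh4.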

How the results depend on the processing

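Each count of changed IDs stayed within 1.5 times its value under every alternative run except the minimum fold. With a change of at least 1 log2 unit required, the counts were 1272 for sh1, 1287 for sh4, 1063 for their mean, 544 for both in the same direction, 809 between sh4 and sh1, and 9 in opposite directions, fewer by construction. Leaving out 1 library at a time gave 7151 to 8354 IDs for sh1, 7672 to 8416 for sh4, 7722 to 8486 for the mean, 5071 to 5442 for both in the same direction, 5669 to 7168 between sh4 and sh1, and 562 to 722 in opposite directions. In these fits the lone library is assumed to vary like the other groups. With the replicate block the counts were 8503, 8836, 8936, 5876, 7345 and 851, in that order, and no call of the named IDs changed, against NC or between sh4 and sh1. Deviations of same-numbered libraries correlated at -0.01 for NC and sh1, 0.12 for NC and sh4, and -0.02 for sh1 and sh4. These values neither establish nor exclude a pairing by replicate number, to which the labels attach no batch. Among the alternatives chosen after seeing the data, voom on the recovered reads kept 5635 of the 5760 IDs changed the same way in both groups. The variance trend on mean FPKM gave 5498 such IDs. The largest shift of the median fold under another scaling was 0.10 log2 units, from rescaling to the mean FPKM sum, between sh4 and sh1. Against NC, the 4 named IDs kept direction and call in 136 of 136 tests, with a largest adjusted p of 0.00043 in limma's test. They were selected from the same data for large changes in both groups. Their stability was thus largely set by the selection and does not speak for other IDs. Between sh4 and sh1, the call was kept in 16 of 17 alternatives for ENSMUSG00000029371, 13 for ENSMUSG00000025491 and 6 for ENSMUSG00000039518, and lost in the others with the same direction. For ENSMUSG00000029378, whose difference of -0.0044 was not past the threshold, the sign turned with total-read scaling (0.0736) and with rescaling to the mean FPKM sum (0.1145) or the larger common sum (0.1169), and leaving out 1 library gave -0.0791 to 0.0702, none of them past the threshold; the cause was not tested. The fits and normalizations planned for deposited counts were not run, nor were gene list tests, since no list matched an ID.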

Other observations

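The counts of IDs changed against NC were planned, while all other tests in this part were chosen after the result was seen. Transcripts that appeared or vanished were few beside those that shifted in level. Only 3 IDs had at most 3 reads in both NC libraries and 30 or more in all 4 knockdown libraries, and 1 ID showed the reverse. Between the knockdown groups, 33 IDs had at most 3 reads in both sh1 libraries and 30 or more in both sh4 libraries, and 10 showed the reverse. The 10 most abundant IDs of a library held 7.97% and 8.08% of its reads in sh1, against 5.87% and 5.98% in NC and 5.77% and 5.68% in sh4.

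A second pattern is that 65.6% of tested IDs in sh1 and 68.1% in sh4 changed against NC. A bias with gene length is argued against as the whole cause. The Spearman correlation of the fold change with recovered length was -0.08 in sh1 and -0.07 in sh4, and removing its trend left 8336 of 8361 calls in number for sh1 and 8595 of 8688 for sh4. Total-read scaling gave 8358 IDs for sh1 and 8705 for sh4. It shifted the median fold against NC by only -0.05 log2 units in sh1 and 0.02 in sh4. The test therefore cannot decide on a larger scaling offset, which stays open. Also open, and untested, are knockdown itself and any difference in culture or library preparation that runs with the groups. With replicates this close (SD between 0.16 and 0.17 log2 units), small differences of either origin pass the threshold.

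The conflict between the mouse-type IDs and the human labels was not resolved by any value. Every one of the 54532 IDs carries the mouse prefix in all 6 libraries, so it is not limited to a group, and the column names in the files match the sample titles. Short features also weigh on FPKM: IDs under 200 bp held between 0.108% and 0.262% of the reads but between 4.87% and 12.4% of the FPKM sum. In each library the highest FPKM value belonged to an ID of 57 bp, at 26594 and 39986 FPKM in NC and between 14679 and 17218 FPKM in the knockdown libraries.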
